A study of Oryza sativa Indica Group with 21 samples.

How the data were processed

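Grain of 21 indica rice lines was sampled at 16 days after fertilization and hybridised, 1 line per array, to a custom Agilent 60K rice array in 1 colour (Cy3). Per the labels, plants grew in a glasshouse without treatment, and each line carries a class of high (11 lines), intermediate (7) or low (3) glycaemic index, from which the groups here were taken. The labels give no replicate arrays of a line, and numbers of lines used here follow the order of deposit and pair nothing. For high GI line 11 the sample title gives the class in full and a second label gives it with a letter missing; it was kept as high GI.

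The deposited intensity values are scanner output, 1 file per array. Per the file headers, they were made with Feature Extraction 11.5.1.1, whose processed signal is background-subtracted and spatially detrended and is not normalized between arrays. The same files hold the median pixel intensity of each spot and of its local background as deposited by the authors. The header names IRGSP5 as the build of the array design, and coordinates of genes were not used here. The authors also deposited a table of log2 values for the same arrays. The submitters' processing notes name limma without a version, and no step is assigned to it. The scale of that table was read from the values: each column followed the array's own quantile-normalized and probe-centred log2 signal (r from 0.926 to 0.980 across probes), its direction was the same, and the column medians lay between -0.05 and 0.05. The baseline on which its probes were centred is unknown, since only 1.95% of probes have a median of 0 over these arrays. The table was used as an alternative only.

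Each array has 62976 spots, of which 1319 are controls and were left out. The log2 processed signal of each array was set relative to its 75th percentile over all probes. Spots marked as non-uniform or population outliers, 983 over the 21 arrays without counting controls, were set missing, and 0 spots were saturated. Spots of a probe were averaged (1114 of 59336 probes were spotted more than once). A probe was kept if it was well above background on at least 3 arrays, which left 44502 probes. Of several probes of a gene the one with the highest mean signal was used, giving 33456 genes, of which 10618 had more than 1 such probe. Probes whose names begin with IMULT, taken here as probes with several targets, stood for 2264 of the genes tested.

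Genes are named by the identifiers in the files, with transcript suffixes removed. The files do not pair identifiers with names, and 0 of the 45643 gene identifiers matched the reference table of gene names. Lists fixed before the data were examined held 62 genes by LOC_Os locus, of which 5 were found. A further 16 lists were to match words in gene descriptions and gave no result, since there were no descriptions to search. They covered storage proteins, starch breakdown, green tissue, embryo and aleurone, cell division, chaperones, ribosome, proteasome, cell wall, seed defence, flavonoids, disease resistance, transposable elements, oil synthesis, glycolysis and transcription factor families.

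The rule fixed in advance for naming genes asked for the 8 largest rises and 8 largest falls past the threshold with a description, for the 5 smallest p-values with a description where under 5 genes passed, and for up to 4 members of each list by smallest p. It names only the 5 listed genes here. The other features were chosen after their values were seen: in each contrast, the 2 brightest with a lower mean and the 2 brightest with a higher mean among those with an unadjusted p under 0.001. The first choice had been the smallest p in each direction. It was replaced by brightness after BGIOSGA022241 had been noticed for its high level and its split among the high GI lines, and because its identifier was recalled, with no table to check it, as possibly that of a gene on the lists, so the statements on that feature are not an independent selection. The smallest p would have named OsIBCD044431 (log2 difference -2.50), BGIOSGA006440 (-2.01), BGIOSGA030524 (1.92) and LOC_Os02g29130 (1.74) for high against low GI. It would have named BGIOSGA006440 (-2.17), BGIOSGA006439 (-1.24), BGIOSGA027686 (1.87) and BGIOSGA033426 (2.57) for intermediate against low GI, and BGIOSGA014684 (-3.23), BGIOSGA017737 (-1.37), OsIBCD001693 (3.51) and BGIOSGA032258 (1.48) for high against intermediate GI. None of these passed (limma adjusted p from 0.378 to 1.00). Features that passed in an alternative with 5 calls or fewer, or that vary together with BGIOSGA022241, were likewise named after their values were seen.

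Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 21 arrays with the 3 classes as the only term, so that all contrasts share 1 estimate of the spread. The contrasts were high against low, intermediate against low and high against intermediate GI, with a moderated F test over the classes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Positive differences are higher in the class named first. Lists with at least 2 members measured were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Single values were compared by two-sided exact permutation of lines unless stated otherwise. A feature not well above background in any line of a class has only a bound there, given as "at least N-fold" from the brighter class mean and, per array of the dimmer class, the higher of the feature's own level and the lowest level among probes well above background.

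The fit was tested on simulated data: class means were removed from the real values, residuals scaled up for the fitted means, labels shuffled, and 200 genes changed by 2-, 4-, 8- or 16-fold, in 10 draws per contrast. The median number of unchanged genes called was 4.5, 2 and 7 for the 3 contrasts in the order above, and fitted changes averaged between 1.00 and 1.01 times those put in. The highest number of unchanged genes called in a draw was 34, 19 and 33. Every line of a class shifted alike in a changed gene, so splits within a class were not simulated.

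Arrays lay on 15 slides, of which 6 held 2 arrays and 4 held 2 classes, and were scanned on 8 days. Alternatives planned before the data were examined were normexp background correction (offset 50), median or quantile scaling, the authors' log2 values, no filter on dim probes or a filter on all 21 arrays, the mean of a gene's probes, slide as a random or fixed block, scan day as a random block, only the classes compared, array weights, a trended and robust variance prior, outlier spots kept, a 2-fold minimum, class as an ordered number, an estimated correlation for lists, and leaving out each array. The normexp correction had been planned on mean spot signals, which the columns used here do not include, so median spot signals took their place. Its offset is added to every signal, so log2 differences of dim features shrink under it. With slide as a fixed block, class differences rest on the 4 slides with 2 classes, whose high GI lines are 2, 3 and 8. Array brightness as a covariate was added after the data were seen.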

Results

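Gene expression was measured in developing grain of indica rice at 16 days after fertilization, while the endosperm fills with starch and storage protein. The 21 arrays came from 21 rice lines, 1 array per line, that the labels place in 3 classes of glycaemic index (GI), a measure of how strongly a starchy food raises blood glucose. There were 11 lines of high GI, 7 of intermediate GI and 3 of low GI. Lines are the replicates, so the spread within a class holds genetic differences between lines together with growth and assay error, which 1 array per line cannot separate. The 75th percentile of the processed signal ran from 189 to 480 over the high GI arrays, from 141 to 421 over the intermediate GI arrays and from 193 to 529 over the low GI arrays. The share of probes well above background was 65.6% ± 4.77 (SD, n = 11) in the high GI class, 65.6% ± 5.87 (SD, n = 7) in the intermediate class and 60.9% ± 5.04 (SD, n = 3) in the low GI class. No difference between classes in these shares or percentiles passed the test (two-sided exact permutation tests, adjusted p = 0.997 for each of the 12 comparisons, which also cover both leading axes of variation). The number of arrays limits the precision of every value, and most of all the 3 low GI lines.

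Of 45643 genes with a probe, 22055 (48.3%) were well above background in all 21 grain samples and 7210 (15.8%) in none. The remaining 16378 genes were above background in some of the lines. Gene models from different sources were detected unequally: 52.3% of the genes numbered BGIOSGA were above background in all lines, against 44.3% of the LOC_Os loci, 38.7% of the OsIBCD entries and 28.4% of the OsIBSD entries. The files give identifiers and do not pair them with gene names or descriptions. A gene name below comes from a list of starch, sucrose, storage protein and regulator genes written with their LOC_Os loci before the data were examined. Of its 62 genes, 5 could be found on the array by locus, and none of the 11 storage protein genes could. Granule-bound starch synthase I (Wx), the gene fixed in advance because it sets amylose content, was not found under its locus. It may be on the array under another identifier, but the files do not pair identifiers with names, so no value is given as that of Wx.

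The first comparison set the ends of the scale against each other and asks which genes the grain of high GI lines uses more or less than that of low GI lines. The levels of the 5 listed genes overlapped between the classes. SSIIc, a soluble starch synthase, was at -2.89 ± 0.83 (SD, n = 11) log2 units relative to the array's 75th percentile in high GI grain and at -2.80 ± 0.70 (SD, n = 3) in low GI grain. DPE2, a disproportionating enzyme that acts on maltose, was at -0.19 ± 0.74 (SD, n = 11) and -0.10 ± 0.84 (SD, n = 3). UGP1, a UDP-glucose pyrophosphorylase, was at 2.92 ± 0.69 (SD, n = 11) and 2.70 ± 0.25 (SD, n = 3).

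RPBF, a DOF transcription factor that acts on storage protein promoters, was bright in every line, at 7.57 ± 0.27 (SD, n = 11) in high GI and 7.70 ± 0.23 (SD, n = 3) in low GI grain. RSR1, an AP2-type regulator of starch synthesis genes, was dim, well above background in 8 of 11 high GI and 1 of 3 low GI lines. None of the 5 genes passed the test (limma, adjusted p = 1.00 over all genes; 0.862 for each adjusted over the list alone). The 95% confidence interval of the high minus low difference ran from -0.59 to 0.33 for RPBF and from -1.12 to 0.94 for DPE2, so a 2-fold lower level in high GI lies outside the first interval and inside the second. The second probe of RPBF was much dimmer and its difference had the other sign, 0.09 against -0.13. As groups, the 2 measured starch synthesis genes and the 2 measured endosperm regulators did not pass the test of a shift (camera with a preset correlation, adjusted p = 0.726 for both; 0.775 with an estimated correlation; fry's directional p = 0.841 and 0.501). Only 2 of 31 listed starch synthesis genes and 2 of 10 listed regulators were measured, so these tests do not speak for either list. On the 1 slide that held both classes, the high GI line was at -1.35 relative to the low GI line for the mean of the starch synthesis genes and at 0.34 for the regulators. Over the 3 scan days that held both classes, 1 of them with the same pair of arrays as the slide, these values ran from -1.35 to -0.16 and from -0.07 to 0.36, against -0.09 and -0.11 over all lines.

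**Figure D1:**
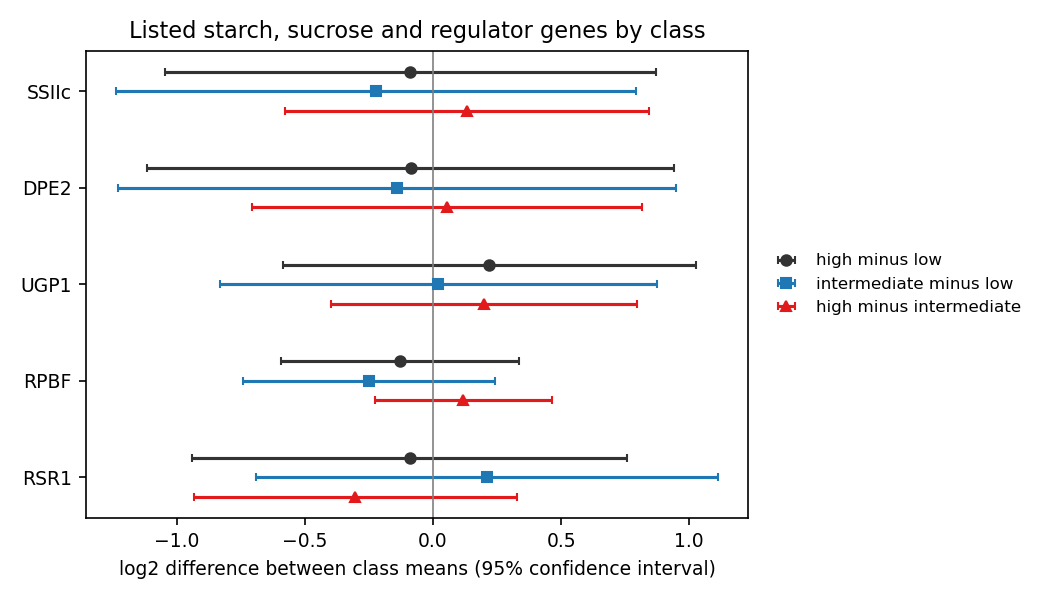
Differences between class means (log2, horizontal axis) for the 5 listed genes, with circles for high minus low, squares for intermediate minus low and triangles for high minus intermediate; bars are 95% confidence intervals from the fit over 11 high, 7 intermediate and 3 low GI lines. Every interval includes 0, and those of RPBF are the narrowest.

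Across all 33456 genes tested, limma called 0 genes between high and low GI grain at an adjusted p under 0.05. At an unadjusted p under 0.05 chance gives 5% of genes on average. Other groupings of the same arrays gave a median of 1172 genes, from 248 to 12989. The real classes gave 535 genes (1.60%), 306 with a higher mean and 229 with a lower mean in high GI. That count was 1938 without low GI line 3, 805 without low GI line 1, 3792 with slide as a fixed block, 6870 with weights per array, 1005 with array brightness as a covariate and 910 without a filter on dim probes. It was 271 with the normexp background correction and 162 with all 21 arrays required above background. The smallest adjusted p was 1.00. Among the features with an unadjusted p under 0.001, the brightest with a lower mean in high GI was BGIOSGA022241, at 4.26 ± 1.63 (SD, n = 11) against 7.35 ± 0.44 (SD, n = 3), a difference of -3.09 (SE 0.79, limma adjusted p = 1.00). BGIOSGA014684 followed at 2.36 ± 1.57 (SD, n = 11) against 5.82 ± 0.92 (SD, n = 3), a difference of -3.47 (SE 0.77, limma adjusted p = 1.00). Two-sided exact permutation tests of the 11 against the 3 lines gave p = 0.0110 and 0.00824 for these features, before any adjustment and after selection on the same data. On each of the 3 scan days that held both classes, with 1 line of each, the high GI line was lower at both features, from -4.49 to -2.31 for BGIOSGA022241 and from -4.74 to -2.69 for BGIOSGA014684. The 1 slide that held both classes is 1 of these 3 pairs. Their high GI lines, 7, 8 and 10, are among the 9 of 11 that lay below every intermediate and low GI line at both features. The agreement therefore follows from that split. High GI lines 9 and 11, the exceptions, were alone on their scan days and do not enter. With slide as a fixed block the differences were -2.58 and -2.98. The second probe of BGIOSGA022241 gave -3.21 and that of BGIOSGA014684 gave -0.07. BGIOSGA022241 was noticed before the ordering by brightness was chosen, and an ordering by the smallest p does not name it.

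The brightest features with a higher mean in high GI were LOC_Os04g14410 and BGIOSGA015957, both not well above background in any of the 3 low GI lines. Against the lowest signal well above background on each low GI array, or the probe's own signal where higher, they were at least 2.39-fold and at least 5.56-fold higher in high GI grain (limma adjusted p = 1.00 for both). The first was well above background in 9 of 11 and the second in 10 of 11 high GI lines. On the 3 scan days that held both classes, with 1 line of each, their differences ran from 0.52 to 2.46 and from 1.81 to 2.74. As log2 values the bounds on class means are 1.26 and 2.47, so some pairs fell below them. Both bounds depend on the background correction, since with normexp the fitted log2 differences of LOC_Os04g14410 and BGIOSGA015957 were 0.29 and 0.57, which lie below them. The second probe of LOC_Os04g14410 was well above background on 1 array, and its difference of 0.36, against 1.49 for the probe used, is not a measured size either.

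The self-test shows what this comparison could have seen if 200 genes changed and every line of a class shifted alike. A change in part of a class, or in few genes, was not simulated and may be recovered less often. With changes added to the observed spread of 33295 genes, 4.40% of 2-fold, 62.6% of 4-fold and 84.4% of 8-fold changes were recovered between 11 and 3 lines. The median 95% interval of a gene's difference was 0.84 log2 units on each side, or 1.79-fold. With weights per array the same comparison called 569 genes, without low GI line 1 it called 5 and without high GI line 11 it called 2. BGIOSGA022241 and BGIOSGA014684 were among the 569 (limma adjusted p = 0.0230 and 0.00677). Of 40 groupings refitted with weights, 5 gave at least as many genes.

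The second comparison asks where intermediate GI grain departs from low GI grain. The levels of the listed genes overlapped here too: RPBF was at 7.45 ± 0.25 (SD, n = 7) against 7.70 ± 0.23 (SD, n = 3), SSIIc at -3.02 ± 0.56 (SD, n = 7) against -2.80 ± 0.70 (SD, n = 3), and UGP1 at 2.72 ± 0.53 (SD, n = 7) against 2.70 ± 0.25 (SD, n = 3). None passed (limma, adjusted p = 1.00 over all genes, 0.961 for each adjusted over the list alone), nor did a list (adjusted p = 0.631 for both; 0.635 with an estimated correlation; fry's directional p = 0.696 for the starch synthesis genes and 0.640 for the regulators). Of single features, BGIOSGA006439 was at -1.19 ± 0.29 (SD, n = 7) in intermediate and 0.05 ± 0.13 (SD, n = 3) in low GI grain, and all 3 low GI lines lay above all 18 others. BGIOSGA027686 had the opposite order, at 0.48 ± 0.56 (SD, n = 7) against -1.38 ± 0.67 (SD, n = 3).

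limma called 0 of the 33456 genes. At an unadjusted p under 0.05 there were 663 genes (1.98%), 389 with a higher and 274 with a lower mean in intermediate GI grain. That count was 1344 without low GI line 3, 1068 without low GI line 1, 3262 with slide as a fixed block, 7775 with weights per array, 1653 with array brightness as a covariate and 1098 without a filter on dim probes. It was 437 with the normexp background correction and 233 with all 21 arrays required above background. The difference of BGIOSGA006439 was -1.24 (SE 0.26) and that of BGIOSGA027686 was 1.87 (SE 0.40), both with a limma adjusted p of 1.00. The second probe of BGIOSGA006439 gave -1.04. Within the 2 scan days that held both classes, and the 1 slide, whose arrays belong to 1 of those days, these features differed in the same direction each time. The classes did not overlap at either feature, so no other outcome was possible. BGIOSGA033426, with a difference of 2.57 (SE 0.58), ran from 1.33 with the normexp background correction to 3.73 over the alternatives. The normexp offset by itself lowers such differences. BGIOSGA028800, with a difference of -1.78 (SE 0.47), was at -0.02 with slide as a fixed block. In the self-test, 5.80% of 2-fold, 55.8% of 4-fold and 82.6% of 8-fold changes were recovered. With weights per array limma called 761 genes, and without low GI line 1 it called 5. BGIOSGA006439, BGIOSGA027686 and BGIOSGA033426 were among the 761 (limma adjusted p = 0.0045, 0.0045 and 0.0213). The 761 were not set against other groupings with weights.

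The third comparison set the larger classes against each other, high GI against intermediate GI grain. RPBF, DPE2 and UGP1 differed by 0.12 (SE 0.17), 0.05 (SE 0.37) and 0.20 (SE 0.29) on the log2 scale. RSR1 differed by -0.30 (SE 0.30) and SSIIc by 0.13 (SE 0.34). None of the 5 passed (limma, adjusted p = 1.00 over all genes; 0.828 to 0.884 adjusted over the list alone), nor did a list (adjusted p = 0.811 for both; 0.813 with an estimated correlation; fry's directional p = 0.771 for the starch synthesis genes and 0.831 for the regulators). The features furthest from 0 relative to their error were the same BGIOSGA014684 and, in the other direction, OsIBCD001693.

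BGIOSGA022241 was at 7.03 ± 0.85 (SD, n = 7) in intermediate GI grain, and the difference of high from intermediate GI grain was -2.77 (SE 0.59, limma adjusted p = 0.688). The high GI class was not uniform: 9 of its 11 lines lay between 2.40 and 4.57, and high GI lines 9 and 11 lay at 6.81 and 7.53, inside the range of the 10 other lines, 5.96 to 8.11. BGIOSGA014684 differed by -3.23 (SE 0.57, limma adjusted p = 0.378) with the same pair of exceptions, and 1 of its 2 probes did not follow, with a difference of -0.06. The 2 probes of BGIOSGA022241 gave -2.77 and -2.82. OsIBCD001693 was higher in high GI grain by 3.51 (SE 0.69, limma adjusted p = 0.487), where 4 of 7 intermediate GI lines lay between -4.38 and -3.64 and the other 3 between 0.46 and 0.70, near the high GI mean of 1.49. The second probe of OsIBCD001693 gave 4.56. Its difference ran from 2.39 to 4.62 over the alternatives and from 1.25 to 6.03 over the scan days with both classes. The dim BGIOSGA032258 was well above background in 7 of 11 high GI lines and 1 of 7 intermediate GI lines, so its difference of 1.48 is not a measured size. The difference was 0.31 with the normexp background correction, whose offset reduces differences of dim features. Within the 3 scan days that held both classes, and the 2 slides, whose arrays make up 1 of those days, these features differed in the same direction each time except BGIOSGA032258, in 2 of 3 scan days. With slide as a fixed block BGIOSGA022241 was at -3.44 and BGIOSGA014684 at -3.85, and with the mean of its probes BGIOSGA014684 was at -1.65. The fixed block draws on high GI lines 2, 3 and 8 only, all among the 9 lower. The scan days draw on these and line 10, also among the 9. Agreement of BGIOSGA022241 and BGIOSGA014684 within slides and scan days therefore follows from their split.

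**Figure D2:**
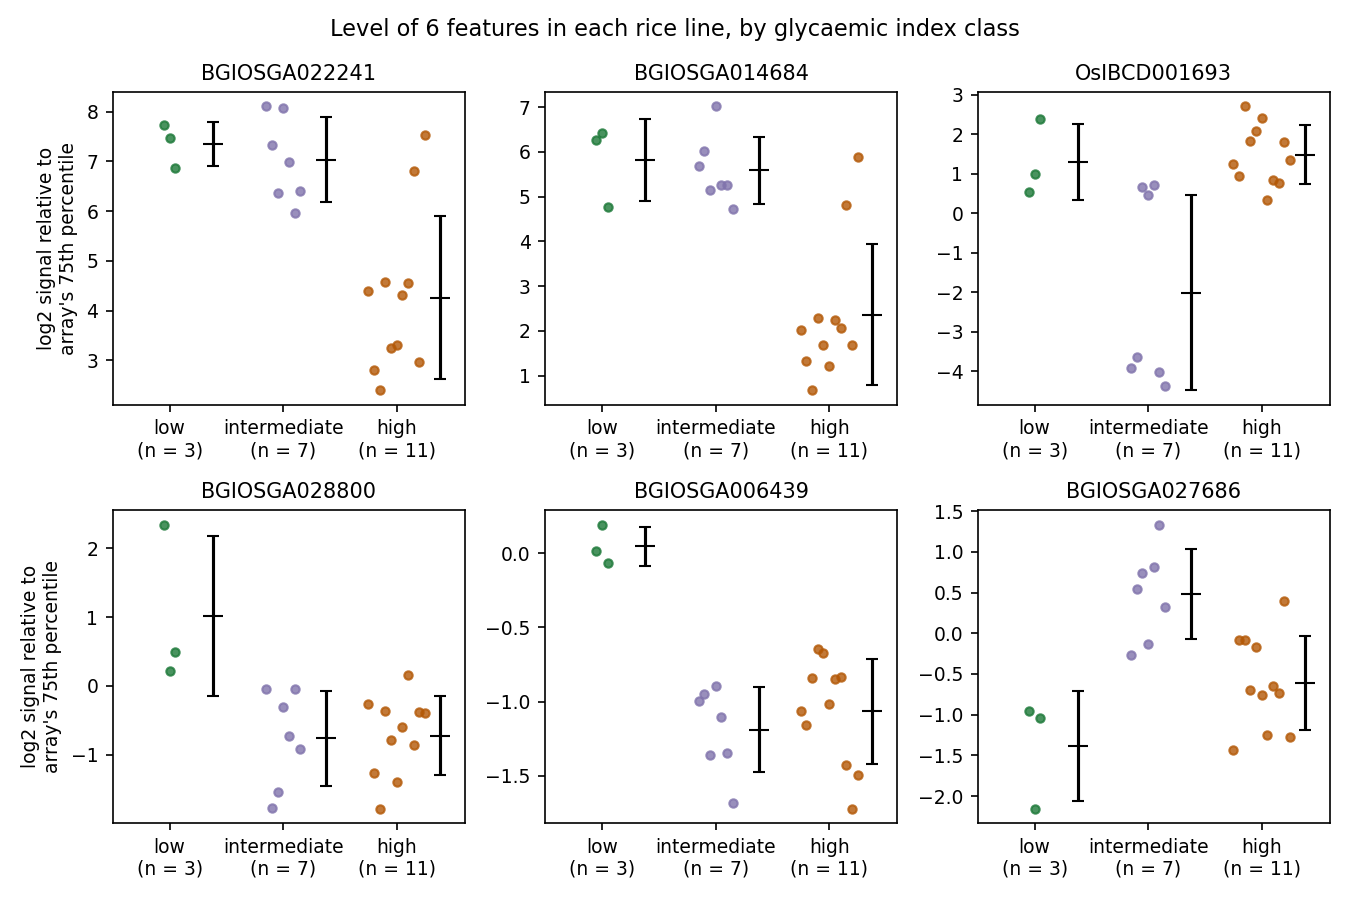
Level of 6 features (log2 signal relative to the array's 75th percentile, vertical axes with their own scales) in each line of the low (n = 3), intermediate (n = 7) and high GI class (n = 11); points are lines and black bars the class mean ± SD. In the BGIOSGA022241 panel 9 of 11 high GI lines lie between 2.40 and 4.57 and the other high GI lines at 6.81 and 7.53; in the OsIBCD001693 panel 4 of 7 intermediate GI lines lie between -4.38 and -3.64.

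limma called 0 of 33456 genes between high and intermediate GI. There were 653 genes at an unadjusted p under 0.05 (1.95%), 319 with a higher and 334 with a lower mean in high GI grain. There were 1292 with slide as a fixed block, 1462 with weights per array, 2065 with array brightness as a covariate and 295 with all 21 arrays required above background. Without high GI line 11, 4 features passed: BGIOSGA014684, BGIOSGA022241, BGIOSGA027393 and OsIBSD047467. Their levels vary together, and they may not be separate genes. Line 11 is among the high GI exceptions at each, so leaving it out narrows their spread. With weights per array 1 passed, BGIOSGA017737. In the self-test, 22.8% of 2-fold, 83.0% of 4-fold and 95% of 8-fold changes were recovered between 11 and 7 lines. These shares do not cover features that split within a class, such as BGIOSGA022241.

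Testing the 3 classes together asks whether any gene differs between any of them. The moderated F test called 0 of 33456 genes, with a smallest adjusted p of 0.326 and 555 genes at an unadjusted p under 0.05. It called 316 genes with weights per array, 5 without high GI line 11, 5 without low GI line 1, 1 without high GI line 9 and 1 with the normexp background correction. The LOC_Os loci carry their chromosome in the identifier, and on none of the 12 chromosomes did the share of loci at an unadjusted p under 0.05 pass a test against all other loci (Fisher's exact tests over 36 chromosome and contrast pairs, smallest adjusted p = 0.944). Closer correlation within than between classes was not detected in the whole profile. The correlation across genes had a mean r of 0.929 between and 0.927 within for high and low GI, 0.931 and 0.931 for intermediate and low GI, and 0.932 and 0.929 for high and intermediate GI (one-sided exact permutation p = 0.610, 0.492 and 0.748, adjusted p = 0.748 for each). Genes are not independent replicates in these correlations. The closest pair, intermediate GI lines 1 and 5, had r = 0.964 and a median absolute difference of 0.32 log2 units, so no sample appeared to be deposited more than once.

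The main axis of variation between arrays followed their brightness. The first principal axis held 28.7% of the variance and followed the log2 75th percentile signal of the array, with Pearson's r = 0.920 and Spearman's rho = 0.913 over 21 arrays (permutation p = 1e-05 for both, the smallest the permutations can give; adjusted p = 2e-05 over 2 relations). Without the 2 arrays furthest from the median brightness r was 0.896. Each array's values had been set relative to this same percentile, so the relation can arise in part from the scaling, which was not tested. Within the high GI class r was 0.925 and within the intermediate class 0.953, and the low GI class has too few arrays. The 3 low GI lines lay at -84.0, -54.3 and 133.2 on this axis, and the lowest of all was high GI line 7 at -142.2. No slide held more than 2 arrays and no scan day more than 5, too few for a value within them.

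**Figure D3:**
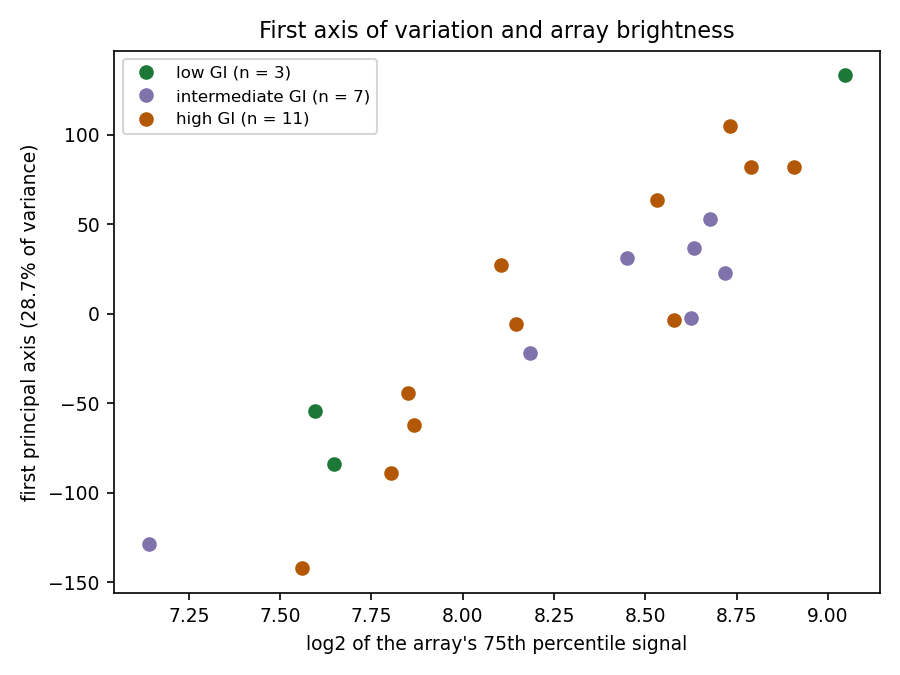
Position of each array on the first principal axis of all genes tested (vertical axis, 28.7% of variance) against the log2 of its 75th percentile signal (horizontal axis); each point is 1 line, coloured by class. The points rise together (r = 0.920), and the 3 low GI arrays lie at -84.0, -54.3 and 133.2, the last being the highest of all.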

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

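The tests of brightness against dim probes and slide were chosen after the result was seen; the spike-in test and the outlier test were not. In 22 measures and features tested for a line far from the rest of the 7 intermediate GI lines, 3 stood out, where chance marks about 1 in 20. BGIOSGA033426 was at -2.21 in intermediate GI line 2 and at -1.05 in the nearest other line (gap over range 0.597). The share of probes well above background was 52.5% in intermediate GI line 4 and 65.9% in the nearest other line (gap over range 0.817). The same line lay at -128.4 on the first axis of variation, with the nearest other line at -21.9 (gap over range 0.587). These 2 measures come from 1 array, whose 75th percentile signal, 141, was the lowest of its class. They are not independent, so the 3 cannot be counted separately against 1 in 20.

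The first axis followed array brightness over all 21 arrays. Dim probes at the floor are argued against, since r was still 0.915 among 21974 genes, the part without a missing value of the 22055 well above background on every array. Slide as the whole cause is argued against by a slide whose arrays lay 195.1 apart out of a range of 275.4, a criterion added after the result, since the first one only compared the mean distance within slides with that over all pairs (88.1 each, one-sided permutation p = 0.505 over 6 slides). A gain that multiplies all signals of an array alike is removed when they are set relative to the 75th percentile. A gain in labelling, hybridization or scanning that differs between probes stays open. The 3 brightest spike-in probes had r = 0.277 with brightness (rho = 0.248, permutation p = 0.227 and 0.278, 95% interval of r from -0.18 to 0.63). Without the 2 extreme arrays r was 0.262. An r under 0.3 had been set in advance to exclude an array-wide gain. That bound was wrong because 21 arrays leave an interval that includes the 0.5 set to support such a gain. Differences between lines in RNA content or grain stage at 16 days are biological alternatives that no label allows to be tested.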

How the results depend on the processing

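The brightness covariate was chosen after the data were seen. Counts of 0 changed genes held in 35 of 38 alternatives for high against low GI, 35 of 37 for intermediate against low, 35 of 37 for high against intermediate and 30 of 35 for the F test, and no list shifted for high against low GI, the contrast for which lists were refitted, in 32. The 2-fold minimum, counted for each contrast, could give only 0, since it selects from the genes already called. Most of the others leave out 1 array, and an array of the third class enters a contrast mainly through the shared spread. The lists tested held 2 measured genes each. Array weights gave 569, 761, 1 and 316 genes (low GI line 2 had a weight of 3.35 and line 3 of 0.23). Normexp gave 1 gene in the F test, BGIOSGA014684. Leaving out single arrays gave 0 to 5, 0 to 5, 0 to 4 and 0 to 5 genes. Calls came without high GI line 11 (2, 0, 4 and 5), without low GI line 1 (5, 5, 0 and 5) and without high GI line 9 (1 in the F test). The cause was not tested, and levels of high GI line 11 are given below. The 5 genes without low GI line 1 were BGIOSGA016409, BGIOSGA038319, LOC_Os06g26090, LOC_Os12g07890 and OsIBCD019710. Those without high GI line 11 were BGIOSGA006444 and BGIOSGA014684 for high against low GI, and for the F test these and BGIOSGA022241, BGIOSGA027393 and OsIBSD047467. High GI line 11 lay apart from most of its class at each of them. It was at 7.53 for BGIOSGA022241. For BGIOSGA006444 it was at -5.64, not well above background, where the other high GI lines lay between -0.59 and 0.85. Leaving out such a line narrows the spread of its class.

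The differences of 3 listed genes, none past the threshold, changed sign for high against low GI. DPE2 was at 0.24 with array weights, between -0.48 and 0.35 with 1 array left out and -1.39 with slide as a fixed block (limma adjusted p = 0.413; 0.413 to 1.00 over its alternatives). SSIIc was at 0.13 with array weights and between -0.31 and 0.31. RSR1 was at 0.53 with slide as a fixed block and between -0.55 and 0.38. The list test was not run for blocks, the robust prior or the brightness covariate, with each of which 0 genes passed. Genes at an unadjusted p under 0.05 numbered 1005, 1653 and 2065 with the covariate, 3792, 3262 and 1292 with slide as a fixed block and 6870, 7775 and 1462 with array weights. For high and intermediate against low GI they numbered 271 and 437 with normexp and 910 and 1098 without a filter on dim probes. Signal over background limited which dim genes were tested: with all 21 arrays required above it, 22055 of 33456 genes were left, of which 162, 233 and 295 had an unadjusted p under 0.05, and the cause was not tested.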

Other observations

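The counts of other groupings and the on/off, neighbour and low GI separation tests were set before their results were seen; the tests on features lower in 9 of 11 high GI lines and the brightness differences of groupings were chosen afterwards. Some features were on in some lines and off in others, with a gap of at least 3 log2 units (8-fold) between 2 sets of at least 2 lines each, the upper set well above background and the lower set not. There were 29 among 33456 genes, 20 of them BGIOSGA, 6 OsIBCD and 3 LOC_Os. On average they were on in 63.6% of the high, 59.6% of the intermediate and 58.6% of the low GI lines, which was not tested. None of the 20 BGIOSGA features lay within 3 identifier numbers of another (0 pairs), and the OsIBCD and LOC_Os features were not searched. Shared gain or loss of neighbours was thus not testable. Probes with several targets made up 3.45% of the 29 on/off features against 6.77% of the other features (Fisher's exact p = 0.720).

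A small share of genes with consecutive BGIOSGA numbers varied together within classes after brightness was removed. The median r of 14460 consecutive pairs was 0.0340, and 256 (1.77%) had r over 0.8, against 0.281% of pairs 1000 numbers apart, and 0.351% of pairs 5 numbers apart. Among probes named IUNQ, the median r of consecutive pairs exceeded that of distant pairs by 0.0341. These are correlations across 21 lines for pairs of genes, and pairs that share a gene are not independent.

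Besides BGIOSGA022241, lower in 9 of 11 high GI lines, there were 7 features with r over 0.85 to it across the 21 lines, the closest being BGIOSGA027393 (r = 0.985, read by a probe named IMULT, taken as one with several targets) and OsIBSD047467 (r = 0.984), and none below -0.85. With array brightness as a covariate the high against intermediate difference of BGIOSGA022241 was -2.86 (SE 0.56). These classes differed by only -0.09 log2 units in mean brightness, so the covariate could move the difference little and does not decide on brightness. Slide as the whole cause is argued against by a difference of -3.44 (SE 0.44) with slide as a fixed block. There, high GI lines differed from the other line of their slide by -4.00 to -2.31 on 3 slides. The fixed block takes class differences only from slides with 2 classes. Their high GI lines, 2, 3 and 8, are all among the 9 lower lines. High GI lines 9 and 11 do not enter the fixed-block difference, so its size is not comparable with that of the main fit. A swap between classes stays open, since the feature was picked for its split, and the 0 of 10 other lines in the range of the 9 follow from that split. A wrong label on high GI lines 9 and 11 cannot be told apart from true variation within the class, such as allelic differences that the labels do not give, since 0 other features passed the threshold to check it. Lines 9 and 11 were each the only array of their slide and scan day, so effects of these cannot be told apart either. High GI line 4, among the 9 lower, was likewise alone on both. At BGIOSGA006444 high GI line 11 lay at -5.64, below every other line, and line 9 at -0.36, near its class. That feature was named after its values were seen and does not settle the label. One transcript read by several features may explain the shared pattern: BGIOSGA014684 followed BGIOSGA022241 within the 7 intermediate GI lines with r = 0.765, between the values set for and against, and its second probe did not follow. Only BGIOSGA014684 was tested in this way. The closer BGIOSGA027393 and OsIBSD047467 were not set against these values and may not be separate genes. Among intermediate GI lines OsIBSD047467 was highest in lines 1 and 4, at 0.17 and 0.55, as was BGIOSGA022241, at 8.11 and 8.07. It was lowest in lines 3 and 6, at -0.88 and -0.87, as was BGIOSGA022241, at 6.37 and 5.96.

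A count of 0 genes is reached by any grouping, so the 100 of 100 groupings of the same arrays, the real one included, that gave at least the 0 genes of each contrast and of the F test say nothing about chance. The highest other gave 4291 for high against low, 5 for intermediate against low, 2 for high against intermediate and 7899 for the F test. Chance could not be excluded for the counts at an unadjusted p under 0.05, where 88 of 100 gave as many as the real 535 (highest other 12989), 77 as many as 663 (8155), 79 as many as 653 (9510) and 81 as many as 555 (13837). Why some groupings gave many times the real count was not tested beyond their difference in brightness. Groupings that differed more in brightness gave more genes at an unadjusted p under 0.05 (Spearman's rho 0.582, 0.698 and 0.515 for the contrasts in the same order, over 100 groupings that share arrays and are not independent). A large difference did not always give calls: for high against low the largest, -0.85 log2 units, gave the 4291 and the next, -0.79, gave 0, and for intermediate against low the largest, 0.90, gave 0. Chance could not be excluded with array weights either, since 5 of 40 groupings gave at least the 569 genes of high against low GI and the highest other gave 12055. All 3 low GI lines lay above or below the 18 others for 10 features (5 and 5), where chance gives 0.150% of features and 86 of 100 sets of 3 arrays gave as many (highest other 3420).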
